A study of Homo sapiens with 4 samples.

How the data were processed

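Total RNA from LX-2 cells was measured on 4 arrays, 2 from cells given vehicle and 2 from cells given CM272 before TGFβ1. Per the labels' protocols, RNA was extracted with TRIzol and cleaned on columns, 300 ng of it was copied into sense-strand cDNA, and this was biotinylated with an Affymetrix whole-transcript kit. The deposited values are log2 signals that the authors made with RMA, per the submitters' processing notes, with 1 value per probe set and array. The array type, the RMA software and its version are not given in the sources used here. The values fitted that scale, with medians of 4.45, 4.45, 4.48 and 4.41 over the 4 arrays. Only the processed value table was used, so the background correction could not be varied. Array data carry no read depth, and the number of arrays limits the precision.

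The table held 48416 rows. Of these 16098 had 1 gene symbol, 0 had several and 32318 had no symbol in the annotation used here. All 16098 symbols were updated through the Entrez identifier to the RefSeq genes of the GRCh38.p14 assembly, which was used only for names and for the order of neighbouring genes. They named 14884 genes, 779 of them with more than 1 row, and the row with the highest mean over the 4 arrays stood for the gene. Genes with a mean log2 level under 5 were left out as dim, which removed 5961 and left 8923. Rows of families with near-identical copies are reported as uncertain.

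Differences between CM272 and vehicle were fitted with limma 3.58.1 (lmFit and eBayes without trend or robust options) in R 4.3.3, on all 4 arrays and with no covariates. The moderated test was 2-sided, with 2 residual and 3.12 prior degrees of freedom, and p-values were adjusted by Benjamini and Hochberg over the 8923 genes, with a threshold of 0.05. At an unadjusted p under 0.05, 4089 genes passed. Permuting the labels of 2 arrays against 2 cannot give a p under 0.333, so no permutation test was used. The labels do not say that the arrays came from separate cultures, so the p-values measure the spread between these samples, which may be technical.

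Gene lists (38) were written from general knowledge, and the 35 with at least 5 tested members were tested with camera at a preset correlation of 0.01, adjusted over the lists. Many fixed members had no named row or were dim, so counts and list tests cover only the tested members. For example, 13 of 24 contractile genes, 16 of 30 direct SMAD targets and 5 of 13 gluconeogenesis and hepatic-type genes were tested. The camera test with an estimated correlation and fry were alternatives. Genes named in the text are the 12 largest rises and 12 largest falls among genes past the threshold whose groups did not overlap, the genes of a fixed list of 20, and up to 4 tested members of each list with the smallest p. That gave 164 genes, of which 149 passed. Of the 20 fixed genes 10 are reported; the others are not reported here. A list of DUX4 target genes was added, after the largest rises had been seen, for a hypothesis in the closing section.

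Samples, groups, the tests of genes and lists, the 38 lists, the naming rule and all alternatives but cyclic loess were chosen before the data were examined. The closing section names its own tests that were chosen later. The alternatives were no limit on dim genes, limits of mean log2 4 and 6, eBayes with trend and robust options, repeated quantile normalization, centring on the median, the mean of all rows of a gene, the replicate number as a block, each array left out in turn, and all rows with or without a symbol. With an array left out, the lone array of its group was assumed to vary like the other group. Cyclic loess normalization was chosen after seeing the data.

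The fit was tested on simulated data for 2 arrays against 2, over 8923 genes of which 200 were changed, 50 at each of 4 sizes. It recovered 4% of changes of 0.5 on the log2 scale, 82% of changes of 1, and 100% of changes of 2 and of 3. Of 152 calls 9 were false. No list was called when none was shifted (0 lists by camera). A list shifted by 0.5 had a camera adjusted p of 2.31e-32 at the preset correlation and 0.189 with an estimated correlation. Genes were simulated independently and with equal spread in both groups, so this does not test camera on lists whose genes move together. The data held more changed genes than the 200 simulated, so the share of changes recovered need not apply to them. Figures were drawn with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.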

Results

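Gene expression was measured in LX-2 cells, an established human hepatic stellate cell line, on 4 microarrays. Stellate cells lay down most of the scar matrix in liver fibrosis, and TGFβ1 is the cytokine that drives them towards the contractile, matrix-producing myofibroblast state. All cells received TGFβ1 at 5 ng/ml for 24 h. In the 24 h before that they had been kept with 400 nM CM272, a reversible inhibitor of the histone methyltransferase G9a and of the DNA methyltransferase DNMT1, or with the DMSO vehicle at 0.01%. Each group held 2 arrays. Cells without TGFβ1 were not analysed here, so the design gives 1 comparison, which asks what CM272 changed in cells under TGFβ1. Across the 8923 tested genes the 2 vehicle arrays correlated at r = 0.993, the 2 CM272 arrays at r = 0.986, and arrays of different groups at r = 0.935 to 0.947; genes are not independent replicates. The SD of the difference between the 2 arrays of a group was 0.164 for vehicle and 0.232 for CM272 on the log2 scale. Effects are log2 fold changes of CM272 minus vehicle, given as estimate ± SE from 2 arrays per group, with limma's Benjamini-Hochberg adjusted p. No calls of detection above background were used, so where a group's mean lay under log2 5 the size of a change is uncertain and no linear fold is given. Among genes of the naming rule this holds for the vehicle level of USP17L12, USP17L9P, TEX14, ZNF280A, SEPTIN4, LINC01554, STXBP5-AS1, TMEM100, ERO1B, RELN, ACSL5, IFIT2, DDIT3, FLT1 and KDR and the CM272 level of SNAR-D and SYN1. Genes said to complete a count lie outside the naming rule and were chosen after their values were seen.

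CM272 changed 2929 of the 8923 tested genes (32.8%), of which 1327 rose and 1602 fell. The balance depended on the scaling, with 1453 higher and 1467 lower after centring each array on its median and 1560 higher and 1384 lower with cyclic loess, which was chosen after seeing the data. Changes of at least 2-fold were mostly rises, with 200 higher and 67 lower among 267 genes (74.9% higher). The germ cell gene TEX14 rose by 4.44 ± 0.13 (adjusted p = 6.19e-04) from a vehicle level of 4.38, its neighbour SEPTIN4 by 4.13 ± 0.15, the zinc finger gene ZNF280A by 4.23 ± 0.27 and the AP-1 transcription factor gene FOSB by 3.59 ± 0.09. The protocadherin gene PCDH10 rose by 3.12 ± 0.14, LINC01554 from a level of 4.40 to 7.40, STXBP5-AS1 by 2.74 ± 0.11, the general transcription factor gene GTF2B by 2.69 ± 0.08, TMEM100 by 2.68 ± 0.13 and ERO1B, an oxidoreductase of the endoplasmic reticulum, by 2.62 ± 0.30. The highest estimate, 4.73 ± 0.11, belonged to USP17L12 and USP17L9P, copies of a deubiquitinase gene family whose rows held identical values on all 4 arrays, so it is uncertain which copy was measured.

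Among the falls, the long RNA LOC100507412 changed by -2.34 ± 0.16 (5.05-fold lower, adjusted p = 0.00277) and the stellate cell transcription factor gene FOXF1 by -1.88 ± 0.12 (3.68-fold lower). The actin-binding smooth muscle gene TAGLN changed by -1.76 ± 0.08, the retrieval receptor gene KDELR3 by -1.72 ± 0.19, the imprinted gene MEST by -1.55 ± 0.08 and PDGFA, a growth factor for stellate cells, by -1.53 ± 0.09. LINC00842 changed by -1.82 ± 0.13 and SNHG18 by -1.57 ± 0.08. The small noncoding RNA genes SNAR-D (-2.32 ± 0.23), SNAR-C1 (-1.94 ± 0.19) and SNAR-B1 (-1.84 ± 0.23) are near-identical copies, and their rows are uncertain as single genes. HOXB4 changed by -1.69 ± 0.23 (adjusted p = 0.00801), a call lost without vehicle replicate 1 or 2 (adjusted p = 0.0551 and 0.0548). Without vehicle replicate 1 or 2, 443 and 431 genes passed, and 228 and 230 of the 267 genes with at least 2-fold changes kept their calls. The spread in such fits came from the CM272 arrays alone, which differed more (SD of the difference 0.232 against 0.164). A call lost there does not by itself show a smaller effect, and no named gene changed sign. Testing all 14884 named genes with no limit on dim signals gave 1286 changed genes, and a stricter limit of mean log2 6 gave 175 genes with at least 2-fold changes.

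**Figure D1:**
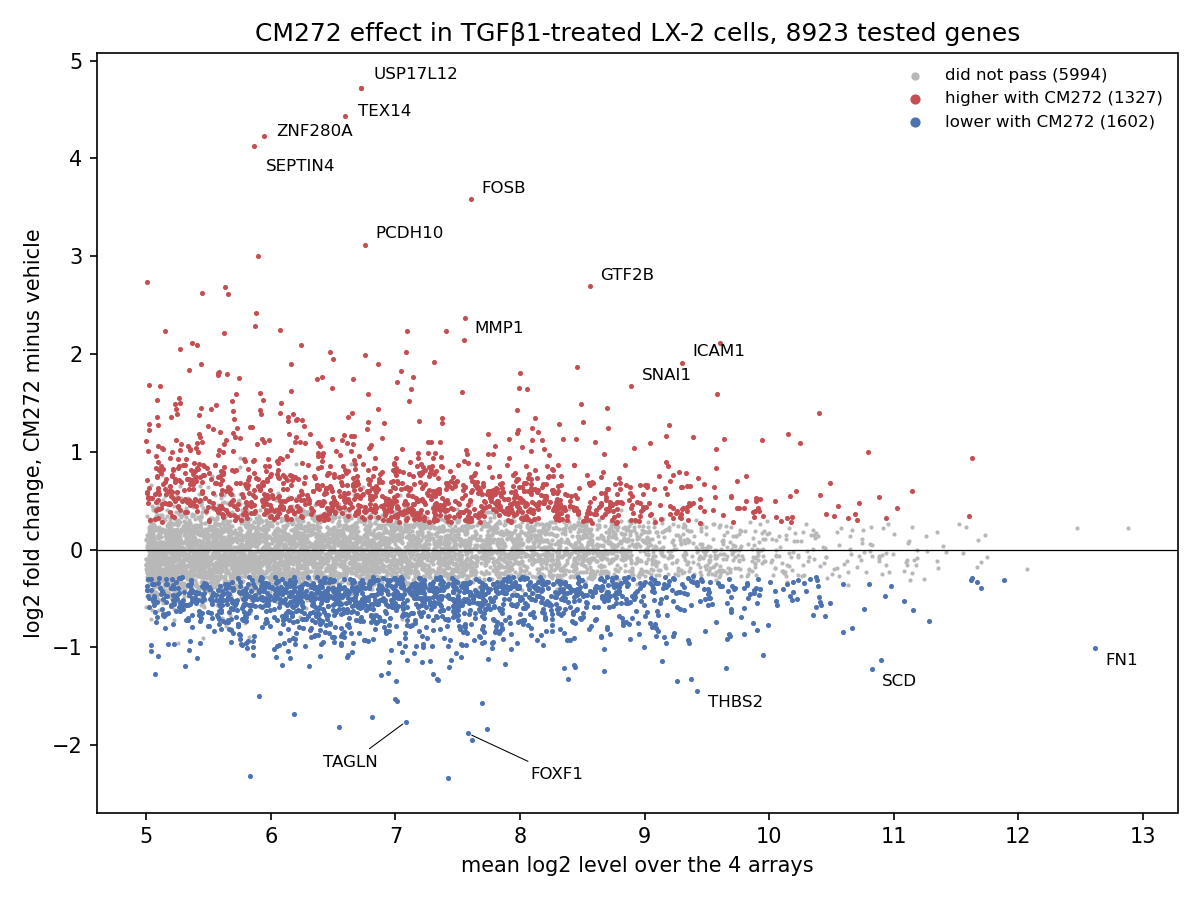
Log2 fold change of CM272 minus vehicle (y axis) against the mean log2 level over the 4 arrays (x axis), with a point for each of the 8923 tested genes. Red points are the 1327 genes that rose, blue points the 1602 that fell and grey points those that did not pass; changes of at least 2-fold lie mostly above 0 (200 against 67).

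Most of the tested matrix and contractile genes of the myofibroblast state fell with CM272. Of 34 matrix genes fixed for the list 10 were tested, of which 8 fell, with a median log2 fold change of -0.51 (camera adjusted p = 0.00121, but adjusted p = 0.444 with an estimated correlation) and 8 falls adjusted over the list alone. Camera with an estimated correlation missed a simulated list shifted by 0.5. A call lost with it, here and below, therefore does not decide against a shift. Thrombospondin-2, THBS2, changed by -1.44 ± 0.10, the proteoglycan gene VCAN by -1.21 ± 0.10 and fibronectin, FN1, by -1.01 ± 0.08 (2.01-fold lower, from 13.12 ± 0.04 to 12.11 ± 0.05, SD, n = 2). FBLN2 changed by -0.75 ± 0.09. Of 13 contractile genes 8 fell, 9 adjusted over the list alone, with a median of -0.62 (camera adjusted p = 0.00515, but adjusted p = 0.444 with an estimated correlation). Besides TAGLN these were led by the tropomyosin gene TPM1 (-0.99 ± 0.08), TGFB1I1 (-0.82 ± 0.08) and PDLIM7 (-0.75 ± 0.08). Without vehicle replicates 1 and 2, 3 and 4 of the 8 matrix calls and 4 and 3 of the 8 contractile calls remained, and THBS2, VCAN, FN1, TAGLN, TPM1 and TGFB1I1 kept theirs. The FBLN2 call was lost without vehicle replicate 1 (adjusted p = 0.0574) and the PDLIM7 call without vehicle replicate 2 (0.0503).

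Of 9 genes of collagen processing and crosslinking, 3 fell and 6 did not pass, with a median of -0.26. Adjusted over the list alone, 7 were lower and 1 higher. The crosslinking enzyme gene LOX changed by -0.84 ± 0.08 (1.79-fold lower, adjusted p = 0.00415), CRTAP by -0.77 ± 0.08 and LOXL1 by -0.56 ± 0.09, while P3H1 had an estimate of 0.28 ± 0.09 (adjusted p = 0.0617). The list as a whole was lower by camera (adjusted p = 0.0415, but adjusted p = 0.444 with an estimated correlation and 0.0540 with the replicate block). That call was lost without vehicle replicate 1 (adjusted p = 0.0570), CM272 replicate 1 (0.0735) or CM272 replicate 2 (0.0797) and at limits of mean log2 4 (0.0757) or 6 (0.0639), within a range of 0.0378 to 0.0797 over the alternatives at the preset correlation. The LOXL1 call was lost without either vehicle array and the CRTAP call without vehicle replicate 1. Without vehicle replicate 1 and 2 the estimates were -0.47 and -0.65 for LOXL1 and -0.73 and -0.80 for CRTAP.

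Metalloproteinases and their inhibitors moved both ways, with 2 of 10 genes higher, 3 lower and 5 that did not pass, the same counts adjusted over the list alone. The interstitial collagenase gene MMP1 rose by 2.15 ± 0.12 (4.43-fold, adjusted p = 0.00200) and MMP19 by 0.62 ± 0.08. The membrane-bound MMP14 changed by -1.03 ± 0.08, the inhibitor gene TIMP1 by -0.51 ± 0.10 and TIMP3, which completes the count, by -0.35. The list did not shift by camera (adjusted p = 0.983), and its median of -0.12 and mean of 0.08 differ in sign. The median was 0.08 without CM272 replicate 2 and 0.12 with no limit on dim genes. With vehicle replicate 1 or 2 left out the adjusted p was 0.108 and 0.116 for TIMP1 and 0.0674 and 0.0610 for MMP19, and 2 of the 5 calls remained in each case, those of MMP1 and MMP14.

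Direct targets of TGF-β signalling through SMAD proteins did not move as a group: 2 of 16 rose, 4 fell and 10 did not pass, also adjusted over the list alone (camera adjusted p = 0.442, median -0.15). SNAI1, a transcription factor gene of the epithelial to mesenchymal transition, rose by 1.67 ± 0.08 and the TGF-β pseudoreceptor gene BAMBI by 1.59 ± 0.14. The related SNAI2 changed by -0.85 ± 0.08, the SMAD repressor gene SKIL by -1.06 ± 0.08, and SKI (-0.69) and LIF (-0.37) complete the count. Of the 6 calls 4 remained without vehicle replicate 1 or 2, those of SNAI1, BAMBI, SNAI2 and SKIL. Of 9 ligands, receptors and signal transducers of the pathway, 4 fell and FST rose, against 7 lower and 1 higher adjusted over the list alone. The coreceptor gene ENG changed by -0.75 ± 0.08, SMAD2 by -0.52 ± 0.08, LTBP3 by -0.39 ± 0.09 and SMAD3, which completes the count, by -0.41, while FST, an activin antagonist gene, rose by 0.62 ± 0.08. This list had a median of -0.31 and did not pass (camera adjusted p = 0.0506). None of its 5 calls held by limma without vehicle replicate 1 or 2, where 4 stayed at an unadjusted p under 0.05 in each case and the adjusted p was 0.0535 and just above 0.05 for ENG, 0.0735 and 0.0820 for SMAD2, 0.0674 and 0.0583 for FST and 0.102 and 0.162 for LTBP3. Without CM272 replicate 2, 3 of the 5 remained and the adjusted p for LTBP3 was 0.0580.

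Of 10 tested genes of quiescent stellate cells, 4 rose, 2 fell and 4 did not pass, with 5 higher and 2 lower adjusted over the list alone. RELN, which encodes the matrix protein reelin and is a stellate cell marker, rose by 2.29 ± 0.19 (adjusted p = 0.00345), BAMBI as above, ECM1 by 0.50 ± 0.08 and PLIN2, a lipid droplet gene completing the count, by 0.51. The lipogenic regulator gene SREBF1 changed by -0.52 ± 0.08 and GATA4, also completing the count, by -0.65. The list did not shift (camera adjusted p = 0.274, median 0.32). Only RELN and BAMBI kept their calls without vehicle replicate 1 or 2, where the adjusted p was 0.0954 and 0.0835 for ECM1 and 0.0691 and 0.0910 for SREBF1. PPARG, a quiescence regulator fixed for inspection, had a mean log2 level of 2.78 with CM272 and lay under the limit for testing in both groups.

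Most of the tested interferon-stimulated genes, which encode antiviral effectors and sensors, rose with CM272. Of 25 tested 19 rose, 1 fell and 5 did not pass, the same counts adjusted over the list alone, with a median log2 fold change of 0.82 (1.76-fold). IFIT2 rose by 1.79 ± 0.08 (adjusted p = 0.00135), OASL by 1.74 ± 0.10, IFI44 by 1.40 ± 0.08 and SAMD9L by 1.12 ± 0.08, and USP18, a negative regulator of interferon signalling that completes the count, changed by -0.40. The list shifted upward by camera (adjusted p = 2.67e-09, but adjusted p = 0.444 with an estimated correlation). IFIT2, OASL, IFI44 and SAMD9L kept their calls without each array in turn, and 11 and 12 of the 20 calls remained without vehicle replicate 1 and 2. Of 20 genes of antigen presentation by MHC class I fixed for the list only 6 had a named row, and no heavy chain gene was among them. Of the 6 tested, 3 rose and 1 fell, also adjusted over the list alone. These 6 did not shift as a list (camera adjusted p = 0.203, median 0.27), which leaves most of the fixed genes unmeasured. The peptide-trimming enzyme genes ERAP2 and ERAP1 rose by 0.85 ± 0.08 and 0.69 ± 0.08, the light chain gene B2M rose by 0.44 ± 0.10, and the chaperone gene CALR changed by -0.31 ± 0.08. Of these, only ERAP2 kept its call without vehicle replicate 1 or 2, where the adjusted p was 0.0619 and 0.0501 for ERAP1, 0.155 and 0.0731 for B2M and 0.177 and 0.191 for CALR. With CM272 replicate 2 left out it was 0.0567 for B2M and 0.0848 for CALR, and 2 of the 4 calls remained.

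Of 16 inflammatory cytokine and NF-kB target genes, 8 rose, 3 fell and 5 did not pass, with 9 higher and 3 lower adjusted over the list alone and a median of 0.32. The adhesion receptor gene ICAM1 rose by 1.91 ± 0.08 (3.76-fold, adjusted p = 0.00130), the prostaglandin synthase gene PTGS2 by 1.90 ± 0.17 and the neutrophil chemokine gene CXCL5 by 1.18 ± 0.10. The chemokine gene CXCL12 changed by -1.08 ± 0.10, and CCL2 (-0.49) and LIF (-0.37) complete the count of falls. The list shifted upward (camera adjusted p = 0.0327, but adjusted p = 0.444 with an estimated correlation), a call lost without CM272 replicate 1 (adjusted p = 0.0735, against 3.61e-04 to 0.0735 over the alternatives at the preset correlation). With vehicle replicate 1 and 2 left out, 7 and 6 of the 11 calls remained, among them ICAM1, PTGS2, CXCL5 and CXCL12.

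In both lists of lipid synthesis most of the tested genes fell with CM272. Of 17 genes of cholesterol synthesis and uptake 11 fell and 6 did not pass, against 12 falls adjusted over the list alone, with a median of -0.42 (camera adjusted p = 8.46e-04, but adjusted p = 0.444 with an estimated correlation). Squalene epoxidase, SQLE, changed by -1.14 ± 0.08 (2.20-fold lower), FDPS by -0.96 ± 0.08, DHCR7 by -0.96 ± 0.08 and ACAT2 by -0.75 ± 0.08. Of 15 genes of fatty acid synthesis and desaturation 9 fell and DGAT1, which makes triglycerides and completes the count, rose by 0.80. Adjusted over the list alone, 10 fell and 1 rose. The stearoyl-CoA desaturase gene SCD changed by -1.23 ± 0.08 (2.34-fold lower, adjusted p = 0.00267), the desaturase genes FADS2 by -0.97 ± 0.08 and FADS1 by -0.89 ± 0.09, and LPIN1 by -0.66 ± 0.08. This list had a median of -0.52 and shifted downward (camera adjusted p = 0.00861, but adjusted p = 0.444 with an estimated correlation). With vehicle replicate 1 and 2 left out, 3 and 5 of the 11 cholesterol calls and 3 of the 10 fatty acid calls in each case remained. The LPIN1 call was lost in both cases (adjusted p = 0.0606 and 0.0608) and the ACAT2 call without vehicle replicate 1 (0.0519).

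**Figure D2:**
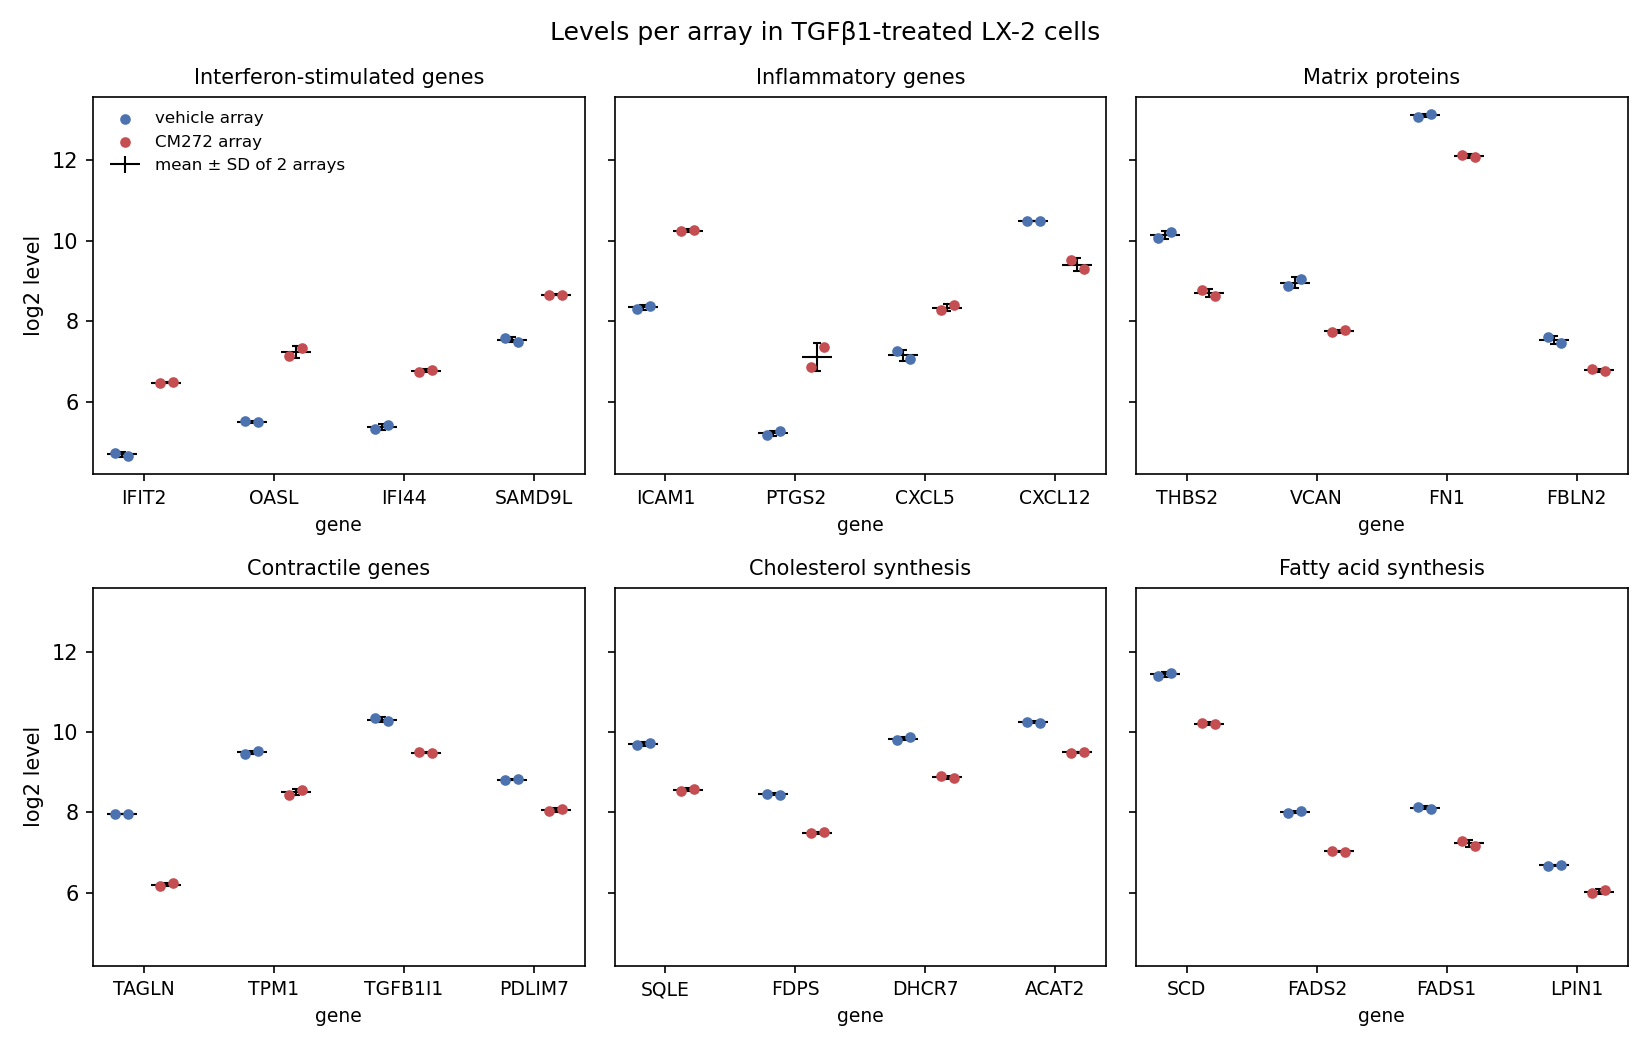
Log2 level (y axis) of 24 genes of 6 gene lists (x axis), with blue points for the 2 vehicle arrays, red points for the 2 CM272 arrays and black marks for the mean ± SD of each group. FN1, for example, lies at 13.12 with vehicle and 12.11 with CM272.

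In central carbon metabolism, most of the tested genes of glycolysis and of oxidative phosphorylation did not pass, and most genes fixed for these lists had no named row. Of 25 glycolysis genes fixed for the list 9 were tested, of which 4 fell and 5 did not pass. Adjusted over the list alone 7 fell, and the median was -0.26. The lactate dehydrogenase genes LDHA and LDHB changed by -0.74 ± 0.10 (1.67-fold lower, adjusted p = 0.00919) and -0.53 ± 0.09, PGK1 by -0.49 ± 0.10 and PGAM1 by -0.45 ± 0.11, while the hexokinase gene HK2 had an estimate of 0.28 ± 0.13 (adjusted p = 0.163). Of 37 oxidative phosphorylation genes fixed for the list 13 were tested, of which 5 rose and 8 did not pass. Adjusted over the list alone 6 were higher and 1 lower, and the median was 0.10. UQCRC2 of complex III rose by 0.55 ± 0.08, the complex IV genes COX7B and COX5B by 0.54 ± 0.08 and 0.37 ± 0.08, OGDH of the citric acid cycle by 0.49 ± 0.09, and COX7A2 (0.38) completes the count. Both lists passed by camera (adjusted p = 0.0415 each), but with adjusted p = 0.546 for glycolysis and adjusted p = 0.444 for oxidative phosphorylation with an estimated correlation. With the replicate block neither passed (camera adjusted p = 0.0540 each). The glycolysis call was lost without vehicle replicate 1 (adjusted p = 0.0624) or CM272 replicate 1 (0.107) and at a limit of mean log2 6 (0.0536), within a range of 0.0228 to 0.107 over the alternatives at the preset correlation. The oxidative phosphorylation call was lost without vehicle replicate 2 (0.0831), CM272 replicate 1 (0.0773) or CM272 replicate 2 (0.0688) and at that limit (0.0654), within a range of 0.0334 to 0.0831 over the same alternatives. None of the 9 single-gene calls in these lists held by limma without vehicle replicate 1 or 2, where all 9 stayed at an unadjusted p under 0.05. The adjusted p was then 0.0702 and 0.0599 for LDHA and 0.0701 and 0.0744 for UQCRC2, and from 0.0698 to 0.156 for LDHB, PGK1, PGAM1, COX7B, OGDH and COX5B. With CM272 replicate 2 left out, 3 of the 5 oxidative phosphorylation calls remained, and the adjusted p for COX5B was 0.0505.

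Other metabolic lists did not shift as groups by camera. Of 12 genes of serine, glycine and one-carbon metabolism 7 fell and 2 rose, also adjusted over the list alone (camera adjusted p = 0.0649, median -0.38). The glycine decarboxylase gene GLDC rose by 1.65 ± 0.08 (3.15-fold) and GLUL, which completes the count, by 0.63, while the serine synthesis genes PSAT1 and PHGDH changed by -1.21 ± 0.09 and -0.83 ± 0.08 and SHMT1 by -0.67 ± 0.09. Of 11 genes of mitochondrial fatty acid oxidation 4 rose and 2 fell, also adjusted over the list alone (camera adjusted p = 0.300, median 0.17, and -0.03 without CM272 replicate 2). The acyl-CoA synthetase gene ACSL5 rose by 1.44 ± 0.19, ACAA2 by 0.62 ± 0.08, ETFDH by 0.62 ± 0.10 and ACSL1, completing the count, by 0.75, while HADH (-0.55 ± 0.09) and ACSL4 (-0.37, completing the count) fell. Of 5 tested genes of gluconeogenesis and hepatic metabolism SIRT1 rose by 0.60 ± 0.09, FOXO1 by 0.45 ± 0.12 and PC by 0.42 ± 0.10, with 3 higher and 1 lower adjusted over the list alone (camera adjusted p = 0.415, median 0.42). Only GLDC, PSAT1, PHGDH and ACSL5 kept their calls without each array in turn. When vehicle replicate 1 or 2 was left out the adjusted p was 0.0545 and 0.0689 for SHMT1, 0.0631 and 0.0626 for ACAA2, 0.0678 and 0.0845 for ETFDH, 0.0911 and 0.0610 for HADH, 0.0734 and 0.0682 for SIRT1, 0.153 and 0.151 for PC and 0.198 and 0.0763 for FOXO1. In each case 3 of 9, 1 of 6 and 0 of 3 calls of the 3 lists remained by limma, and 2 and 3 calls of the last list stood at an unadjusted p under 0.05. Without CM272 replicate 2 the adjusted p was 0.0624 for PC and 0.0928 for FOXO1, and 1 of these 3 calls remained.

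Among the genes of the compound's named targets, DNMT1 had an estimate of 0.07 ± 0.08 (adjusted p = 0.526) and its partner UHRF1 one of 0.24 ± 0.11 (adjusted p = 0.157). EHMT2, which encodes G9a, changed by -0.28 ± 0.08 (1.22-fold lower, adjusted p = 0.0444) and its partner EHMT1 by -0.37 ± 0.09 (adjusted p = 0.0308). Of 16 genes of H3K9 methylation, which include writers, readers and demethylases, 5 fell (TRIM28 at -0.47 ± 0.08, CBX3 at -0.34 ± 0.08, EHMT1, EHMT2 and the demethylase gene KDM3A, which completes the count, at -0.44) and ATF7IP rose by 0.62 ± 0.09, with 6 lower and 1 higher adjusted over the list alone. Of 11 genes of the DNA methylation machinery only ZBTB33 passed (-0.58 ± 0.15, adjusted p = 0.0384), and adjusted over the list alone 0 passed by limma, with 1 at an unadjusted p under 0.05. MBD1 had an estimate of 0.22 ± 0.10 and MBD2 one of -0.22 ± 0.10 (adjusted p = 0.150 and 0.160). Neither list shifted (camera adjusted p = 0.415 and 0.799; the second had a median of 0.05 and an upward test beside a mean of -0.03). The EHMT2 call was lost without any 1 of the 4 arrays (adjusted p = 0.236 and 0.176 without vehicle replicates 1 and 2, 0.0736 and 0.0783 without CM272 replicates 1 and 2). The EHMT1 call was lost without vehicle replicate 1 (0.180), vehicle replicate 2 (0.123) or CM272 replicate 1 (0.0601). Leaving out vehicle replicate 1 or 2 gave an adjusted p of 0.0705 and 0.0647 for ATF7IP, 0.0940 and 0.0863 for TRIM28, 0.185 and 0.124 for CBX3 and 0.0996 and 0.176 for ZBTB33. In both cases 0 calls of either list remained by limma, with 3 and 4 of the 6 H3K9 calls at an unadjusted p under 0.05 and 1 and 0 of the DNA methylation list. The adjusted p was 0.0532 for CBX3 without CM272 replicate 1, where 2 of the 6 H3K9 calls remained, and 0.0622 for ZBTB33 without CM272 replicate 2.

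In groups of genes often held silent by methylation, 6 of 11 imprinted genes and 1 of 12 neuronal genes passed, while only 1 germline gene could be tested. Of 16 named germline genes only TEX14 reached the limit of 5 on the mean of the 4 arrays. It did so only through its CM272 level (4.38 with vehicle, 8.82 with CM272), so that it was the one tested follows from its rise. Over the 16 the median level was 3.36 with vehicle and 3.30 with CM272. Of 11 imprinted genes 5 rose and MEST fell, with 5 higher and 2 lower adjusted over the list alone (camera adjusted p = 0.294, median 0.27). The retrotransposon-derived PEG10 rose by 1.30 ± 0.08 (2.47-fold, adjusted p = 0.00267), KCNQ1OT1 by 0.66 ± 0.11 and IGF2R by 0.55 ± 0.08, and MEG3 (0.44) and RTL1 (0.40) complete the count. Of 12 neuronal genes repressed by REST only SYT11 rose (0.40 ± 0.08), also adjusted over the list alone, while L1CAM (-0.35 ± 0.11), SYN1 (-0.61 ± 0.24) and VGF (0.26 ± 0.11) did not pass (adjusted p = 0.0671, 0.111 and 0.132). The neuronal list did not shift (camera adjusted p = 0.799, with an upward test beside a median of -0.0065 and a mean of -0.04). This median was above 0 after repeated quantile normalization (0.02), median centring (0.01) and cyclic loess (0.04) and without vehicle replicate 1 (0.01) or CM272 replicate 2 (0.11). TEX14, MEST and PEG10 kept their calls without each array in turn. Of the 6 imprinted calls 2 remained without vehicle replicate 1 or 2, and the adjusted p was then 0.0801 and 0.0838 for KCNQ1OT1, 0.0766 and 0.0682 for IGF2R and 0.121 and 0.117 for SYT11.

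Proliferation genes moved in both directions. Of 25 genes of DNA replication and the G1/S transition 9 rose and 3 fell, also adjusted over the list alone (camera adjusted p = 0.0506, median 0.18). The helicase gene MCM6 rose by 0.86 ± 0.09, CCNE2 by 0.86 ± 0.14 and the sliding clamp gene PCNA by 0.60 ± 0.09, while GINS1 (-0.56 ± 0.08), MCM2 (-0.38) and SLBP (-0.33) fell, the last 2 completing the count. Of 37 genes of mitosis 7 rose and 6 fell, against 8 and 8 adjusted over the list alone (camera adjusted p = 0.729, with an upward test beside a median of -0.0097 and a mean of 0.02). This median too was above 0 after quantile normalization (0.03), median centring (0.0081) and cyclic loess (0.04) and without vehicle replicate 2 (0.02) or CM272 replicate 2 (7.07e-04). The kinase gene TTK rose by 0.74 ± 0.08, the phosphatase gene CDC25C by 0.98 ± 0.13 and NUSAP1 by 0.51 ± 0.08, while CCNF changed by -0.79 ± 0.11. Of 16 p53 target genes 4 rose and 1 fell, also adjusted over the list alone (camera adjusted p = 0.415, median 0.05). ACER2 rose by 1.15 ± 0.20, PLK2 by 0.79 ± 0.09, SESN2 by 0.55 ± 0.12 and SESN1, completing the count, by 0.34, and the apoptosis gene BAX changed by -0.73 ± 0.11. Of the 12, 13 and 5 calls of these lists 1, 0 and 0 remained by limma without vehicle replicate 1 (10, 9 and 5 at an unadjusted p under 0.05), and 1, 2 and 0 without vehicle replicate 2 (9, 11 and 4). Of the 12 replication calls 7 remained without CM272 replicate 2. MCM6 was kept in all cases, while without vehicle replicate 1 and 2 the adjusted p was 0.0806 and 0.0659 for CCNE2, 0.0767 and 0.0796 for PCNA, 0.0535 and 0.0492 for TTK, 0.0598 and 0.0453 for CCNF and 0.0772 and 0.0591 for BAX. It ran from just above 0.05 to 0.123 for GINS1, CDC25C, NUSAP1, PLK2, ACER2 and SESN2.

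In the stress response lists, calls of the ATF4 and hypoxia genes went both ways. Of 14 genes of the ATF4 pathway and the unfolded protein response 3 rose and 5 fell, also adjusted over the list alone (camera adjusted p = 0.415, median -0.23). The transcription factor genes ATF3 and DDIT3 rose by 2.02 ± 0.29 and 1.81 ± 0.10 and SESN2 as above, while XBP1 changed by -1.32 ± 0.13 and the asparagine synthetase gene ASNS by -0.77 ± 0.12, and DDIT4 (-0.91), MANF (-0.62) and SDF2L1 (-0.34) complete the count. Of 14 hypoxia response genes 2 rose and 5 fell, against 4 and 6 adjusted over the list alone (camera adjusted p = 0.780, median -0.11). The vasodilator peptide gene ADM rose by 1.31 ± 0.09 and NDRG1 by 0.95 ± 0.08, while VEGFA (-0.92 ± 0.08), LOX, BNIP3 (-0.86), ERO1A (-0.61) and KDM3A (-0.44) fell, 3 of them completing the count. Of 10 NRF2 antioxidant genes 4 fell and 6 did not pass, against 4 lower and 1 higher adjusted over the list alone (camera adjusted p = 0.284, median -0.20). These were glutathione reductase, GSR (-0.81 ± 0.08), HMOX1 (-0.69 ± 0.09), TKT (-0.67 ± 0.08) and SRXN1 (-0.35 ± 0.08). Of 11 metallothionein and heat shock genes BAG3 (-0.51 ± 0.09) and MT1E (-0.45 ± 0.10) fell, also adjusted over the list alone (camera adjusted p = 0.799, median 0.10, and -0.0076 without vehicle replicate 1), and the near-identical copies in this list are uncertain as single genes. DDIT3, XBP1, ADM, NDRG1, VEGFA, LOX and GSR kept their calls without each array in turn. In the 4 lists, 2, 4, 1 and 0 calls remained by limma without vehicle replicate 1 and 2, 5, 1 and 0 without vehicle replicate 2, where both calls of the last list stayed at an unadjusted p under 0.05. The adjusted p was then 0.0616 and 0.0574 for ATF3, 0.0504 and 0.0706 for ASNS, 0.0532 and 0.0628 for HMOX1, 0.0610 and 0.0549 for TKT, 0.191 and 0.130 for SRXN1, 0.0684 and 0.0986 for BAG3, 0.112 and 0.151 for MT1E and 0.0641 and 0.123 for SESN2. Without CM272 replicate 2 it was 0.0718 for SRXN1.

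Of 25 genes of autophagy and lysosomes 9 rose, 2 fell and 14 did not pass, also adjusted over the list alone, with a median of 0.16 (camera adjusted p = 0.0263, but adjusted p = 0.444 with an estimated correlation). TP53INP2 rose by 0.98 ± 0.10 (1.97-fold, adjusted p = 0.00504), ATG12 by 0.64 ± 0.10 and the sialidase gene NEU1 by 0.59 ± 0.09, while the kinase gene ULK1 changed by -0.79 ± 0.12 and ATG7, completing the count, by -0.43. The list call was lost without CM272 replicate 1 (adjusted p = 0.0613, against 0.0207 to 0.0613 over the alternatives at the preset correlation). Only TP53INP2 of the 11 calls remained without vehicle replicate 1 or 2, with adjusted p of 0.0766 and 0.0559 for ATG12, 0.0720 and 0.0767 for NEU1 and 0.0699 and 0.0653 for ULK1. Of 15 YAP/TEAD target genes ANKRD1 rose by 0.77 ± 0.08 and DLC1 (-0.39 ± 0.08), TEAD1 (-0.44 ± 0.09) and MYOF (-0.33 ± 0.09) fell, also adjusted over the list alone (camera adjusted p = 0.396, median -0.15). None of these 4 calls held by limma without vehicle replicate 1 or 2 (adjusted p = 0.0530 and 0.0501 for ANKRD1 and from 0.111 to 0.195 for the others), where 3 stayed at an unadjusted p under 0.05 in each case. The MYOF call was also lost without CM272 replicate 1 (0.0811).

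Of the lists fixed as controls, 9 of 21 cytosolic ribosomal protein genes fell and 12 did not pass, against 10 falls adjusted over the list alone, with a median of -0.28 (camera adjusted p = 0.00328, but adjusted p = 0.444 with an estimated correlation). RPL10A changed by -0.64 ± 0.08, RPS16 by -0.55 ± 0.10, RPS3 by -0.52 ± 0.10 and RPS19 by -0.43 ± 0.08. None of the 9 calls held by limma without vehicle replicate 1 or 2, where 7 and 8 stayed at an unadjusted p under 0.05 and the adjusted p was 0.0679 and 0.0629 for RPL10A and from 0.0979 to 0.117 for RPS16, RPS3 and RPS19. The list call held in both cases (camera adjusted p = 0.00318 and 0.0169, the latter the highest over the alternatives at the preset correlation). Of 19 immediate early genes 5 rose and 4 fell, also adjusted over the list alone (camera adjusted p = 0.755, with an upward test and a mean of 0.33 beside a median of -0.06). Besides FOSB and ATF3, EGR1 rose by 1.27 ± 0.09, DUSP5 by 0.73 ± 0.08 and FOS, completing the count, by 1.01, while KLF2 (-0.72 ± 0.08), MYC (-0.61), KLF6 (-0.41) and IER3 (-0.33) fell, 3 of them completing the count. Of 9 housekeeping genes PGK1 and EEF2 (-0.39 ± 0.09) fell and B2M rose, also adjusted over the list alone (camera adjusted p = 0.415, median -0.10), and VCP had an estimate of -0.22 ± 0.09 (adjusted p = 0.118). FOSB and EGR1 kept their calls without vehicle replicate 1 or 2, where 3 and 2 of the 9 immediate early calls and 0 of the 3 housekeeping calls remained by limma, the latter with 3 and 2 at an unadjusted p under 0.05. The adjusted p was then 0.0530 and 0.0501 for DUSP5, 0.0519 and 0.0577 for KLF2, 0.0767 and 0.129 for PGK1, 0.135 and 0.158 for EEF2, 0.0616 and 0.0574 for ATF3 and 0.155 and 0.0731 for B2M. Without CM272 replicate 2 it was 0.0630 for EEF2 and 0.0567 for B2M, and 1 of the 3 housekeeping calls remained.

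Markers of other liver cell types were mostly dim. The 15 named hepatocyte markers had a median level of 3.92 with vehicle and 3.95 with CM272, and 0 were bright enough to be tested. Of 4 tested epithelial markers the keratin genes KRT18 (-0.89 ± 0.08) and KRT8 (-0.85 ± 0.15) fell, and ANXA4 (0.63 ± 0.10) and SOX9 (0.57 ± 0.09) rose, also adjusted over the list alone. Of 5 tested endothelial markers the VEGF receptor genes FLT1 and KDR rose by 2.11 ± 0.16 (adjusted p = 0.00322) and 1.03 ± 0.18 from dim vehicle levels (4.31 and 4.62), and FCN3 (-0.44 ± 0.09) and TIE1 (-0.44 ± 0.12) fell, also adjusted over the list alone (camera adjusted p = 0.674, median 0.05, but -0.03 without vehicle replicate 2 and -0.14 without CM272 replicate 1). Of 5 tested leukocyte and Kupffer cell markers CD14 rose by 1.08 ± 0.08 and NKG7 fell (-0.51 ± 0.13), also adjusted over the list alone (camera adjusted p = 0.983, with an upward test beside a median of -0.11 and a mean of -0.02). CSF1R had an estimate of -0.57 ± 0.32 and CD8A one of -0.11 ± 0.08 (adjusted p = 0.228 and 0.356). The brightest of the 5, CD68, lies outside the naming rule and stood at 9.65 with vehicle and 9.67 with CM272. With vehicle, CD14 (5.08) and NKG7 (5.84) lay near the limit of 5 for dim signals. KRT18, FLT1 and CD14 kept their calls without each array in turn. In the epithelial, endothelial and leukocyte lists 1 call each remained without vehicle replicate 1 or 2, where the adjusted p was 0.0807 and 0.0559 for KRT8, 0.0629 and 0.0818 for SOX9, 0.0672 and 0.0821 for ANXA4, just above 0.05 and 0.0744 for KDR, 0.139 and 0.0763 for FCN3, 0.192 and 0.144 for TIE1 and 0.150 for NKG7 in both cases. Without CM272 replicate 2 it was 0.0741 for TIE1.

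**Figure D3:**
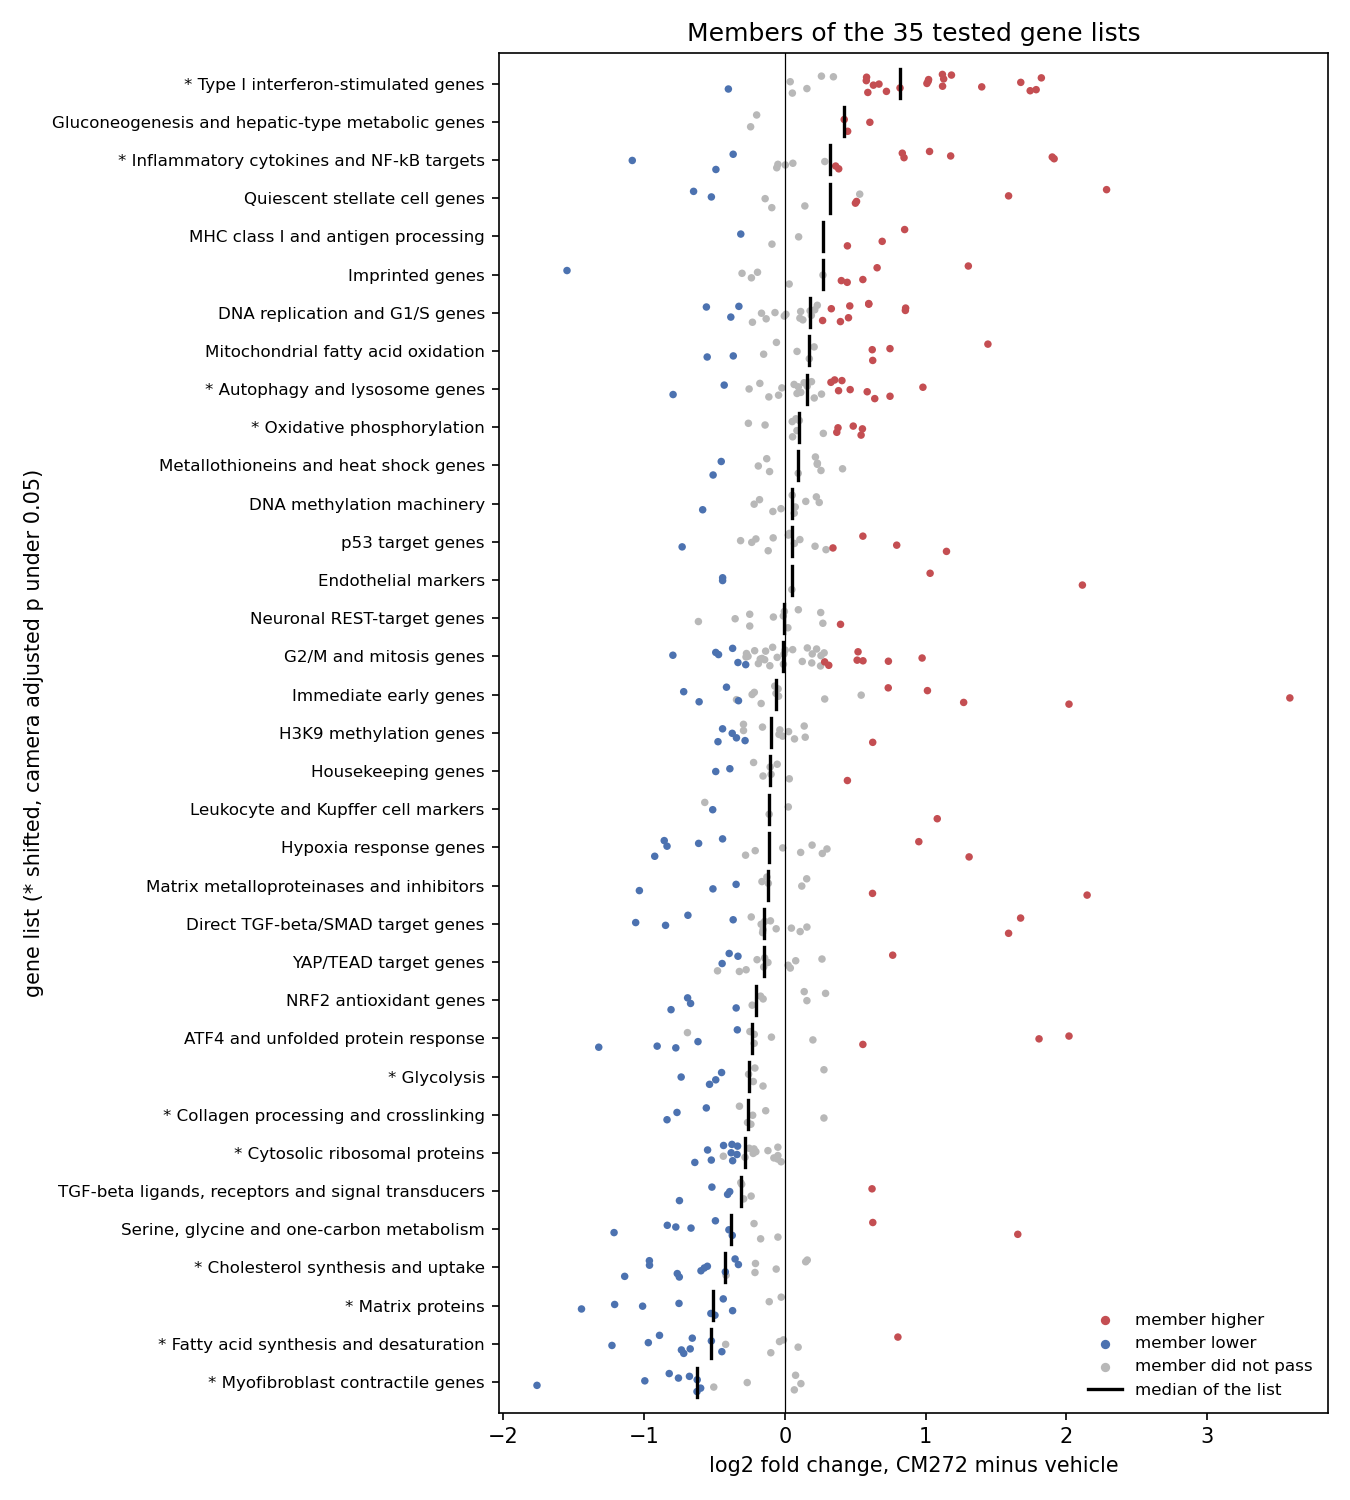
Log2 fold change of CM272 minus vehicle (x axis) of each tested member of the 35 tested gene lists (y axis, ordered by median), with red points for members that rose, blue for those that fell, grey for those that did not pass and a black bar for the median of the list. The 11 lists with an asterisk passed by camera at the preset correlation, 4 upward and 7 downward, and the interferon-stimulated genes have the highest median (0.82) and the contractile genes the lowest (-0.62).

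Over the 35 tested lists, 11 passed by camera with the preset correlation and 0 with a correlation estimated from these arrays, where 2 lists had an unadjusted p under 0.05 and the lowest adjusted p was 0.444. The estimated correlation lay above the preset 0.01 for glycolysis (0.178), fatty acid synthesis (0.0897) and ribosomal proteins (0.0374). It lay under 0.01 for the other called lists (-0.0083 for interferon-stimulated genes), so a high correlation between genes does not account for the loss of those calls. With an estimated correlation camera also missed a simulated list shifted by 0.5 (adjusted p = 0.189), so calls lost with it do not decide against a shift. The test fry, which asks whether the genes of a list move on balance one way, called 21. With 2 arrays per group the number of arrays limits the precision, and the labels do not say that the arrays came from separate cultures, so the p-values measure the spread between these samples, which may be technical.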

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

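The rows in this part lie outside the comparisons by gene, and no test here was chosen after a result was seen, apart from the choice of the rows named. Of the 18779 rows with a mean log2 level of at least 5, 9328 had no gene symbol in the annotation used here. Tested with limma together with the named rows, 2099 of the unnamed rows passed. More of these were higher (1110) than lower (989) with CM272, and at least 2-fold changes were mostly rises (277 higher, 70 lower). The largest rises were those of the probe sets 16965009 and 16965017, at 4.89 ± 0.10 and 4.81 ± 0.10 on the log2 scale. Probe set 16965009 lay at 4.62 and 4.43 on the vehicle arrays and at 9.40 and 9.44 on the CM272 arrays. The named rows of USP17L12 and USP17L9P rose by a like amount (4.73 ± 0.11) between like levels (4.36 and 9.08), and the 5 largest unnamed rises have IDs that lie close to theirs. An ID names no gene, so what these rows measure stays open, and no explanation was tested for them.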

How the results depend on the processing

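The cyclic loess test was chosen only after the results were seen. None of the 164 named genes changed sign under any alternative (0 genes), nor did the median of a list shifted by camera (0 lists), but the medians of 6 other lists did, 2 of them under another scaling. The balance of 1327 higher and 1602 lower genes turned with cyclic loess (1560 and 1384), without a limit on dim genes and without vehicle replicate 1 (266 and 177) or 2. CM272 changed 2929 genes, and 2274 to 3674 under the other limits on dim genes, variance model, normalizations and row choices apart from those that follow. Without a limit on dim genes it changed 1286 (675 higher, 611 lower), where the added dim genes were noisier (median SD within groups 0.188 against 0.0917), and over all rows with or without a symbol 4596. Leaving out 1 array gave 431 to 3317 changed genes, 258 to 1544 higher and 173 to 1773 lower. The 443 and 431 without vehicle replicate 1 or 2 follow from a fit whose spread then came from the CM272 arrays alone, which differed more (SD of the difference 0.232 against 0.164). Genes changed at least 2-fold numbered 267 and, at a limit of mean log2 6, 175, with fewer genes tested (6140), against 236 to 330 without 1 array. Camera shifted 11 lists, 0 with an estimated correlation (2 at an unadjusted p under 0.05), 6 to 10 without 1 array, 9 at mean log2 6, 14 without a limit and 14 with cyclic loess; fry called 21, and the cause of these differences was not tested. The list of TGF-β transducers passed in 6 of these camera settings, that of DNA replication in 6 and that of serine metabolism in 2 (lowest adjusted p = 0.0165, 0.0367 and 0.0334). Same-numbered arrays shared no clear deviation (correlation 0.0253), though the labels do not say whether the numbers pair the arrays. With the replicate block 2859 genes passed (1315 higher, 1544 lower), 267 at least 2-fold, and 8 lists. The lists of collagen processing, glycolysis and oxidative phosphorylation then had an adjusted p of 0.0540. Of the 164 named genes, 80 and 76 lost their call without vehicle replicate 1 and 2, 4 and 11 without CM272 replicate 1 and 2, 36 without a limit on dim genes and 0 to 16 in the other settings. Under the limit on dim signals 5961 genes were not tested.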

Other observations

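The genes of this paragraph were chosen after their values were seen, and of the tests in this part, the comparison of identical USP17L rows and the shuffles by rank and without 2-fold changes were chosen only after the result was seen. Several of the largest changes lay beside each other on the genome. TEX14 (4.44 ± 0.13) and SEPTIN4 (4.13 ± 0.15) are neighbours, and the next gene, RAD51C, rose by 0.55 ± 0.08, while MTMR4 and TRIM37 on the outer sides did not pass. The axon guidance gene SLIT2 rose by 2.12 ± 0.09 with SLIT2-IT1 (2.37 ± 0.09) and MIR218-1 (1.10 ± 0.12) inside it, transcripts that the array may not tell apart. In the HOXB cluster 5 of 6 tested HOX genes fell (median -1.14): HOXB2 changed by -1.33 ± 0.10, HOXB3 by -1.34 ± 0.17, HOXB4 by -1.69 ± 0.23, HOXB7 by -0.39 ± 0.08 and HOXB9 by -0.96 ± 0.09. The antisense gene HOXB-AS3 beside HOXB4 did not pass (-0.10 ± 0.09, adjusted p = 0.440), nor did HOXB6 (-0.14 ± 0.10), and the HOXB4 call was lost without vehicle replicate 1 or 2 (adjusted p = 0.0551 and 0.0548). In the HOXC cluster 0 of 5 passed by limma, with 0 at an unadjusted p under 0.05, and in the HOXD cluster HOXD1 rose by 0.96 ± 0.09 from a dim vehicle level of 4.60 while HOXD10 (-0.90 ± 0.11) and HOXD11 (-0.49 ± 0.11) fell, out of 4. The pair of SLIT2 and SLIT2-IT1 is left out of the neighbour correlation below (r = 0.0497). Genes inside SLIT2 that do not overlap each other are not left out by its rule.

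Effects of neighbouring genes were weakly correlated. Across genes, which are not independent replicates, r was 0.0927 over 8895 neighbouring pairs and 0.0497 over the 7751 that neither overlapped nor shared a symbol root. The latter lay above the highest of 1000 shuffles (0.0345) and of 1000 shuffles within 20 bins of level (0.0356). This argues against a shared level, and against probes shared within the pairs left out, as the whole cause. Pairs inside a common host gene were kept where their members did not overlap each other. By rank (rho = 0.0304) and over the 7305 pairs without 2-fold changes (r = 0.0266) the relation lay under the highest of 1000 shuffles of its own kind (0.0365 and 0.0430), with 4 and 14 shuffles as high, though above the upper bound of their central 95% (0.0232 and 0.0242), and leaving out large changes lowers r whatever the cause. The same 7751 pairs gave r of -0.0129 and 0.0136 for the differences between replicates, under the bootstrap bound of 0.0179 set for shared array noise. The spread of these replicate values was not estimated, so they do not settle whether such noise was shared. A change spread over chromosome regions stays open, since r at 10 steps was 0.0250 with bootstrap bounds (0.00515 to 0.0452) that overlapped those of neighbours (0.0179 to 0.0847), and such overlap excludes no spread, so the bound set for it was not decisive.

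Of 21 cytosolic ribosomal protein genes, fixed as a control list, 9 fell with CM272 and 12 did not pass (median -0.28, and -0.34 to -0.24 over the alternatives). The list call by camera was lost with an estimated correlation (adjusted p = 0.444), a setting that also missed a simulated list shifted by 0.5. Without vehicle replicate 1 or 2, 0 of the 9 calls remained by limma, with 7 and 8 at an unadjusted p under 0.05. Of 10000 random lists matched on level 0.35% had a median as low (95% of them from -0.21 to 0.15), which argues against a fall of all bright probe sets. The median was still -0.24 without vehicle replicate 2, whose removal shrank it most, which argues against 1 array as the cause. An effect of CM272 on these genes stays a hypothesis, since it was found and tested on the same arrays.

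USP17L12, USP17L9P and ZNF280A, among the largest rises, belong to genes that the embryonic transcription factor DUX4 can switch on. The other 27 DUX4 targets measured had a median log2 fold change of 0.0537 (highest 0.68). In the fit without a limit on dim genes 1 rise, of TRIM43 (0.68 ± 0.10), and 1 fall, of SRSF8 (-0.55 ± 0.10), passed limma's threshold. TRIM43B had an estimate of 0.65 ± 0.20 and did not pass (adjusted p = 0.119). The values met the limits set against an active DUX4 program and show no broad rise of its targets. Of the 27 targets 23 had a mean level under 5, among them ZSCAN4 (2.65) and TRIM43 (2.63), while the USP17L rows lay at 4.36 with vehicle. Probe sets that dim may miss a rise, so weak DUX4 activity is not excluded. The rows of USP17L12 and USP17L9P differed by 0 on each array, so probes shared between copies of the family may explain that both rose. Which copies rose stays open.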
